A study of Mus musculus with 6 samples.

How the data were processed

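RNA sequencing of a mouse spermatogonial stem cell line was analysed from 6 libraries in 3 groups of 2. Per the labels, the cells grew on mitomycin-treated mouse embryonic fibroblast feeders in a medium that also held EGF, LIF and FGF2. The PTC group received 10 ng/mL GDNF, the NTC group received no GDNF, and in the LOVA group 5 uM lovastatin took the place of GDNF. Cells were collected on day 18. RNA libraries were strand-specific and sequenced as paired ends. The labels do not say whether the libraries of a group came from separate cultures, so each p of a single gene measures the spread between these libraries.

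The deposited table holds raw counts per Ensembl gene, as whole numbers with no normalization. The submitters' notes name Trimmomatic, Bowtie2, RSEM and DESeq2 without versions or roles, and the mouse build mm10. If RSEM made the counts, they are estimates that were rounded before deposit, and the deposited table does not settle this. The table has 31384 genes, of which 7358 had no count in any library. Symbols and coordinates came from GENCODE M21, which matched 31363 gene identifiers and left 21 without a symbol. The table holds 0 mitochondrially encoded genes, so the mitochondrial share of the RNA could not be computed. Libraries are called A and B after the letters of the deposited columns. The labels number the libraries of a group instead, and nothing pairs the letters with those numbers.

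Total counts ranged from 12454671 to 22668087 per library. A floor of 3 counts corresponded to between 0.128 and 0.258 CPM (counts scaled to a common library total), depending on the library. CPM values used library totals scaled by TMM, while shares of counts and the floor over a group used total counts. Floors cover counting error only, since PCR copies were not marked; intervals of fold changes come from the fit and include the spread between libraries.

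Genes were kept by edgeR's filterByExpr on the 3 groups, which left 16121 genes tested. Libraries were scaled by TMM, and all 6 libraries were fitted with 1 coefficient per group in edgeR 4.0.16 (robust dispersions and a robust quasi-likelihood fit, legacy form). The fit left 3 residual degrees of freedom before moderation, and the common biological coefficient of variation was 0.260. The 3 contrasts were NTC minus PTC, LOVA minus NTC and LOVA minus PTC. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 from the quasi-likelihood F test, over all genes tested. Standard errors (SE) of log2 fold changes came from the same fit. Computations ran in R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0.

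A set of 30 gene lists was fixed, of which 29 had a tested gene; the list of mitochondrially encoded mRNAs had none. The lists covered self-renewal and germ cell identity, differentiation and meiosis, sterol, fatty acid and isoprenoid metabolism, YAP signalling, inflammation, interferon response, cell death, stress, proliferation and glycolysis. Further lists held markers of feeder fibroblasts, Sertoli, Leydig, endothelial and macrophage cells and of spermatids. Each list was tested with camera at a preset correlation between genes of 0.01, and p was adjusted over the lists within a contrast. Such a camera p sets the genes of a list against the other genes at an assumed correlation. It does not measure the spread between libraries. The tests were repeated with an estimated correlation and with fry. List members were counted over all genes tested and also with p adjusted over the list alone. The contrasts, tests, lists, alternatives and the rule for named genes were chosen before the data were examined, except where a choice is said to have been made later.

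Named genes followed that rule. For each contrast it took the 8 highest and 8 lowest log2 fold changes among called genes with a mean CPM of at least 5 and no overlap between the groups, leaving out predicted genes, clones and pseudogenes. It added 10 genes in every contrast, among them Gfra1, Ret, Etv5, Bcl6b, Zbtb16, Kit and Hmgcs1. It also added up to 4 called members of each list with the largest change, or 2 abundant members where none was called. Some of the genes and 1 of the lists so chosen are not reported here; counts of genes and lists include them.

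Overlaps of called genes were set beside the number that independence gives. Correlations and covariances of fold changes that share a group were set beside 100 simulations of unchanged groups with the same shared libraries. Methods were tested on simulated data with 200 genes changed, per contrast. Of genes changed 4-fold, 72%, 76% and 77% were recovered in the 3 contrasts, and of genes changed 2-fold, 9%, 7% and 13%. No changed gene was called with the wrong sign, and 15, 9 and 5 unchanged genes were called. Beside the changed genes recovered, these false calls were a larger share than 0.05 in NTC minus PTC and LOVA minus NTC. In LOVA minus PTC they were close to it. The adjusted p can thus understate the share of false calls.

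The alternatives were RLE and upper-quartile scaling, no low-count filter, a strict filter (CPM of at least 1 in 2 libraries and a mean of at least 5), DESeq2, limma-voom, fits of the 2 compared groups alone, a block by column letter, 2 stricter thresholds and leaving out each library in turn. Where a group was left with 1 library, that library was assumed to vary like the others. Chosen after the data were seen were scaling to the pan-germ-cell genes, leaving out 3 genes of the ribosomal DNA locus, the feeder score as a covariate and a list of 20 further macrophage genes.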

Results

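The data are gene counts from 6 RNA libraries of mouse spermatogonial stem cells grown on fibroblast feeders for 18 days, 2 libraries each with GDNF (PTC), without GDNF (NTC) and with lovastatin in its place (LOVA). GDNF is the growth factor that sustains self-renewal of these stem cells through the receptor Ret and its co-receptor Gfra1, and lovastatin is a statin, a drug that inhibits cholesterol synthesis. Total counts were 14991211 and 22668087 in PTC A and B, 12454671 and 16573315 in NTC A and B, and 13685015 and 12464642 in LOVA A and B. The first principal component of log2 CPM held 76.3% of the variance and the second 8.44%, and PTC libraries lay apart from the other groups on the first. The order of the libraries on it was PTC A, PTC B, LOVA A, NTC A, NTC B and LOVA B. That is also the order of their feeder shares, given below, so this component does not separate group from feeder content.

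Shares of counts from marker genes differed between PTC and the other groups, and the macrophage share also between NTC and LOVA. Pan-germ-cell genes took 0.556% ± 0.00613 (SD, n = 2) of counts in PTC, 0.258% ± 0.0750 in NTC and 0.283% ± 0.120 in LOVA. Feeder fibroblast markers took 0.362% ± 0.334, 2.28% ± 0.761 and 2.21% ± 0.946 in the same order. Macrophage markers took 0.0233% ± 0.00256 in PTC, 0.196% ± 0.0302 in NTC and 0.0427% ± 0.00463 in LOVA. In every group the B library had the larger feeder share, with 0.126% and 0.598% in PTC A and B, 1.74% and 2.82% in NTC, and 1.55% and 2.88% in LOVA. The 20 most abundant genes took 5.01% ± 0.213 of counts in PTC, 9.05% ± 1.44 in NTC and 9.06% ± 1.83 in LOVA.

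**Figure D1:**
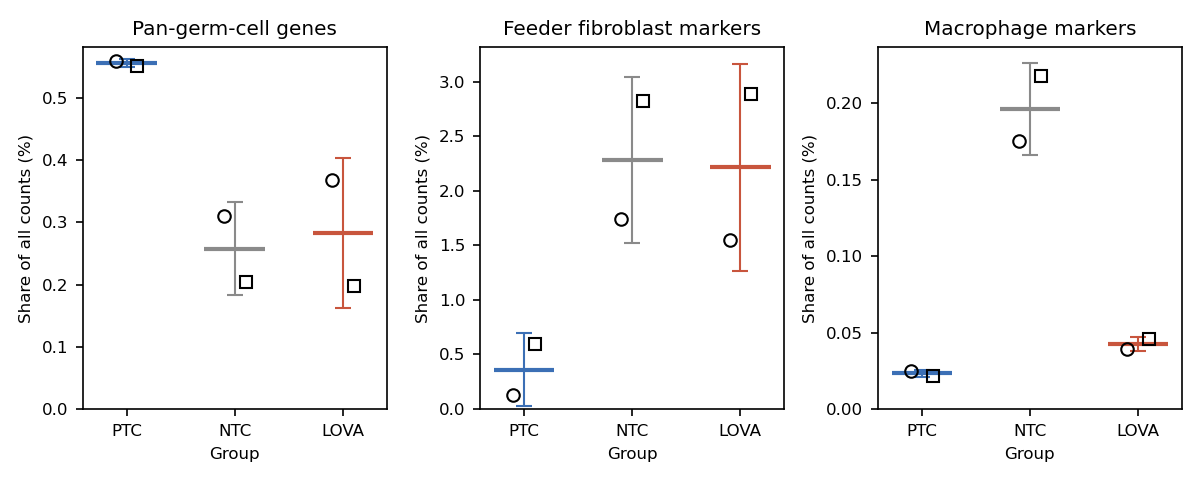
Percent of each library's counts from feeder fibroblast, pan-germ-cell and macrophage marker genes, by group; points are libraries (circle A, square B), lines are means and bars are 1 SD (n = 2). The macrophage share was 0.196% in NTC, against 0.0233% in PTC and 0.0427% in LOVA, while the feeder share was 2.28% in NTC and 2.21% in LOVA.

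NTC minus PTC shows what changed when GDNF was left out. Many self-renewal transcripts fell, and most inflammatory, macrophage and fibroblast transcripts of the lists rose in NTC. Lhx1, a homeobox transcription factor among the GDNF-responsive genes of cultured stem cells, fell from 11.8 ± 3.87 CPM to 0.400 ± 0.110 CPM (SD, n = 2 per group), a log2 fold change of -4.87 (SE 0.52, adjusted p = 0.00795). Ret, the GDNF receptor, fell from 245 ± 65.2 to 61.2 ± 10.0 CPM (4.01-fold lower, log2 SE 0.31, 95% interval of the log2 fold change -2.73 to -1.28, adjusted p = 0.010). Zbtb16, a transcription factor needed to maintain the stem cells, fell from 388 ± 1.09 to 130 ± 6.39 CPM (-1.58, SE 0.26, adjusted p = 0.0109). Saa3, an acute-phase protein, rose from 4.66 ± 1.36 to 123 ± 2.06 CPM (4.71, SE 0.35, adjusted p = 0.00795). In each of these genes both NTC libraries lay beyond both PTC libraries. Without NTC B, which left 1 NTC library, these genes lost their calls. Their log2 fold changes were then -4.60 for Lhx1, -1.84 for Ret, -1.53 for Zbtb16 and 4.70 for Saa3. Lhx1 (ENSMUSG00000018698) lies on chromosome 11 from 84518284 to 84525535, and Ret (ENSMUSG00000030110) on chromosome 6 from 118151745 to 118197718.

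Of the 13 measured GDNF-responsive genes, 7 fell and 1 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -1.14 (camera adjusted p = 9.44e-04; adjusted p = 0.649 with an estimated correlation). Its members Nanos2, an RNA-binding protein that keeps stem cells undifferentiated, and Pou3f1, a transcription factor, fell by 2.03 (SE 0.39) and 1.72 (SE 0.34). Of the 19 undifferentiated spermatogonia markers, 11 fell (13 adjusted over the list alone) and none rose, with a median of -1.19 (adjusted p = 6.06e-06; 0.649 as the adjusted p with an estimated correlation). Bcl6b also fell (-1.14, SE 0.34, adjusted p = 0.0413), while Gfra1 (-0.69, adjusted p = 0.0565), Etv5 (-0.41, adjusted p = 0.322) and the differentiation receptor Kit (0.17, adjusted p = 0.733) did not pass the test. Of the 19 pan-germ-cell genes, 11 fell (17 adjusted over the list alone), among them Tdrd9 (-1.85) and Tdrd5 (-1.38) of the piRNA pathway and Dppa4 (-1.57), with a median of -1.04 (adjusted p = 6.06e-06; 0.649 as the adjusted p with an estimated correlation). Of the 24 proliferation genes, 12 fell (15 adjusted over the list alone), such as the mitotic regulators Cdc20 (-1.53) and Ccnb1 (-1.39), with a median of -0.93 that became 0.07 when libraries were scaled to the pan-germ-cell genes. Camera gave the proliferation list an adjusted p of 1.60e-05, and an adjusted p of 0.649 with an estimated correlation. With that scaling, which moved the median of all genes by 1.05, the medians of the GDNF-responsive, undifferentiated and pan-germ-cell lists were -0.11, -0.17 and -0.04. The last of these was largely set by the scaling itself, which used the counts of those genes. Ret and Nanos2 were then at -0.98 (adjusted p = 0.0528) and -1.02 (adjusted p = 0.0623), and Lhx1 remained called at -3.86. Zbtb16 (-0.54, adjusted p = 0.179) and Bcl6b (-0.11, adjusted p = 0.807) lost their calls, and Gfra1 and Etv5 turned to 0.38 and 0.65, not called. Feeder shares were higher and pan-germ-cell shares lower in both NTC libraries than in both PTC libraries. Of the 126 named genes of this contrast 115 were called, and without NTC B all 115 lost their call; without PTC A 51, NTC A 30, PTC B 28, LOVA A 9 and LOVA B 9 did.

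**Figure D2:**
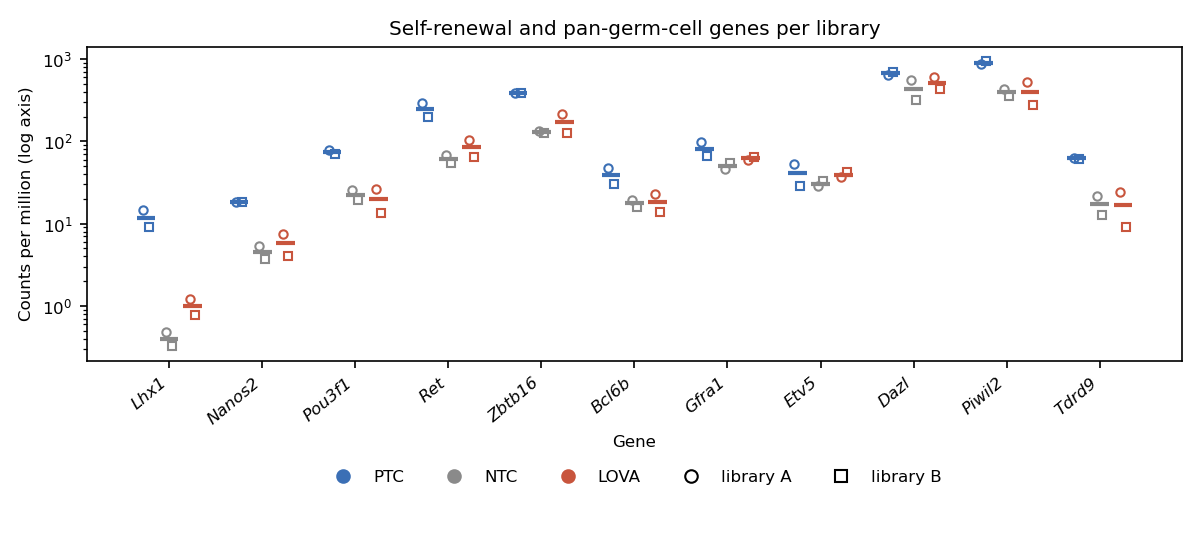
CPM on a log axis of self-renewal and germ cell genes; points are libraries (circle A, square B) and bars are group means (n = 2). Lhx1 was at 11.8 CPM in PTC, 0.400 in NTC and 0.992 in LOVA, and Ret at 245, 61.2 and 84.8.

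Of the 22 measured inflammatory and NF-kB genes, 20 rose (20 adjusted over the list alone), led by Saa3, the iron-binding protein Lcn2 (4.39, SE 0.45) and the chemokine Cxcl5 (4.34, SE 0.68). Their median was 3.23 (camera adjusted p = 1.41e-13; adjusted p = 0.649 with an estimated correlation), and the macrophage share of counts rose with them. All 10 macrophage markers rose, among them Fcer1g (3.93), Adgre1 (3.30) and Tyrobp (3.29), with a median of 2.98 (adjusted p = 6.95e-11; 0.649 as the adjusted p with an estimated correlation). Of the 21 feeder fibroblast markers, 14 rose (21 adjusted over the list alone), such as the collagen-binding Dcn (3.87, SE 0.75) and the protease Mmp2 (109 ± 96.9 against 1747 ± 579 CPM), with a median of 3.02 (adjusted p = 1.06e-06; 0.649 as the adjusted p with an estimated correlation). Of the 22 YAP and TAZ targets, 14 rose and 1 fell (the same adjusted over the list alone), such as the clotting factor receptor F3 (3.65) and Igfbp3 (3.34), with a median of 2.09 (adjusted p = 9.44e-04). Of the 17 p53 targets, 11 rose (12 adjusted over the list alone), including the cell cycle inhibitor Cdkn1a (2.72) and Perp (3.02), with a median of 0.95 (adjusted p = 4.35e-04). For these YAP and p53 lists too the adjusted p was 0.649 with an estimated correlation. The feeder share of counts was 0.362% in PTC and 2.28% in NTC beside them. Whether the 2 lists rose within germ cells or with the feeder share was not tested. By fry, the inflammatory and macrophage lists kept adjusted p of 0.0369 and 0.0281, and 7 of the 10 lists called by camera did not pass. Without NTC B, PTC A, NTC A, PTC B, LOVA A and LOVA B the 10 list calls all held, while single genes lost calls as given for this contrast (all 115 called named genes without NTC B, 51 without PTC A, 30 without NTC A, 28 without PTC B, 9 without LOVA A and 9 without LOVA B).

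The sterol lists were not called in NTC minus PTC. Of the 20 cholesterol synthesis genes 6 fell, 2 rose and 12 were not called (8 lower and 2 higher adjusted over the list alone), with a median of -0.18 that became 0.89 with libraries scaled to the pan-germ-cell genes. Hmgcs1, an enzyme of that synthesis, was at -0.25 (SE 0.18, adjusted p = 0.304) and turned to 0.83 with that scaling, not called. The medians of the other uncalled lists were 1.04 for anti-apoptotic genes, 0.07 for pro-apoptotic genes, 1.09 for interferon-stimulated genes, 1.31 for LXR targets, 0.35 for unfolded protein and integrated stress genes, 0.56 for ERK feedback genes and 0.08 for immediate early and heat shock genes. They were -0.37 for meiotic genes, -0.62 for differentiating spermatogonia markers, -0.74 for pluripotency genes, -0.81 for glycolysis genes, -0.28 for fatty acid synthesis genes and -0.83 for spermatid genes. With libraries scaled to the pan-germ-cell genes these 6 turned to 0.64, 0.40, 0.29, 0.27, 0.74 and 0.24. By fry, LXR targets (adjusted p = 0.0369), pro-apoptotic genes (0.0281) and unfolded protein and integrated stress genes (0.0281) passed as higher. For SREBP2 uptake and regulator genes the median was -0.03 and the mean 0.02 (median 1.05 with that scaling), and for isoprenoid and prenylation enzymes 0.02. Sertoli, Leydig and endothelial markers had medians of 1.18, 1.47 and 0.20, the endothelial test pointing down against its median. Single members moved strongly in some of these lists, such as the pluripotency factors Sox2 (-4.88) and Pou5f1 (-1.73), which fell, and the death receptor Fas (3.55), which rose. Sox2, Pou5f1 and Fas were not called without NTC B (adjusted p = 0.0611, 0.170 and 0.060), nor was Pou5f1 without PTC A (0.0859) or PTC B (0.0524). Single libraries also decided list calls: differentiating markers passed camera without PTC A (0.0284) or NTC A (0.0230), glycolysis genes without PTC B (0.0285), Sertoli markers without PTC B (0.00717) or NTC B (0.0368) and meiotic genes without NTC A (0.00672). Anti-apoptotic genes passed without NTC A (0.0263), LOVA A (0.0276) or LOVA B (0.0268).

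The lowest fold change in NTC among genes with the required counts belonged to the homeobox gene Barhl2 (-5.11, SE 0.45, 24.1 ± 5.97 against 0.704 ± 0.357 CPM). Mpzl2, Mpped1, Zic1, Foxo6, Nefm and Fgd5 also lay low, from -3.42 to -2.69. The highest belonged to Pakap (6.15, SE 1.55), which overlaps other genes and had 4 counts in PTC, the matrix proteases Mmp13 (5.92), Mmp10 (5.76, 9 counts in PTC) and Mmp3 (5.38, SE 0.72), and the BMP antagonist Grem1 (5.44). Kng1, Ces1a and Il1rn lay at 5.85, 5.59 and 5.41; Kng1 and Ces1a have close paralogs, and Ces1a had 7 counts in PTC. In all, edgeR called 3472 genes higher and 2086 lower in NTC than in PTC, of which 2950 and 932 changed at least 2-fold. Without PTC A the counts were 1210 higher and 201 lower, without PTC B 2294 and 473, without NTC A 2251 and 535, and without NTC B 1 and 0, the 1 gene being AY036118, named after its value was seen. With libraries scaled to the pan-germ-cell genes 5185 genes were higher and 40 lower. Barhl2, Mpzl2, Mpped1, Foxo6, Zic1 and Fgd5 stayed called lower with that scaling, from -4.12 to -1.67, as did Sox2 (-3.83). Nefm (-1.82, adjusted p = 0.0551) lost its call.

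**Figure D3:**
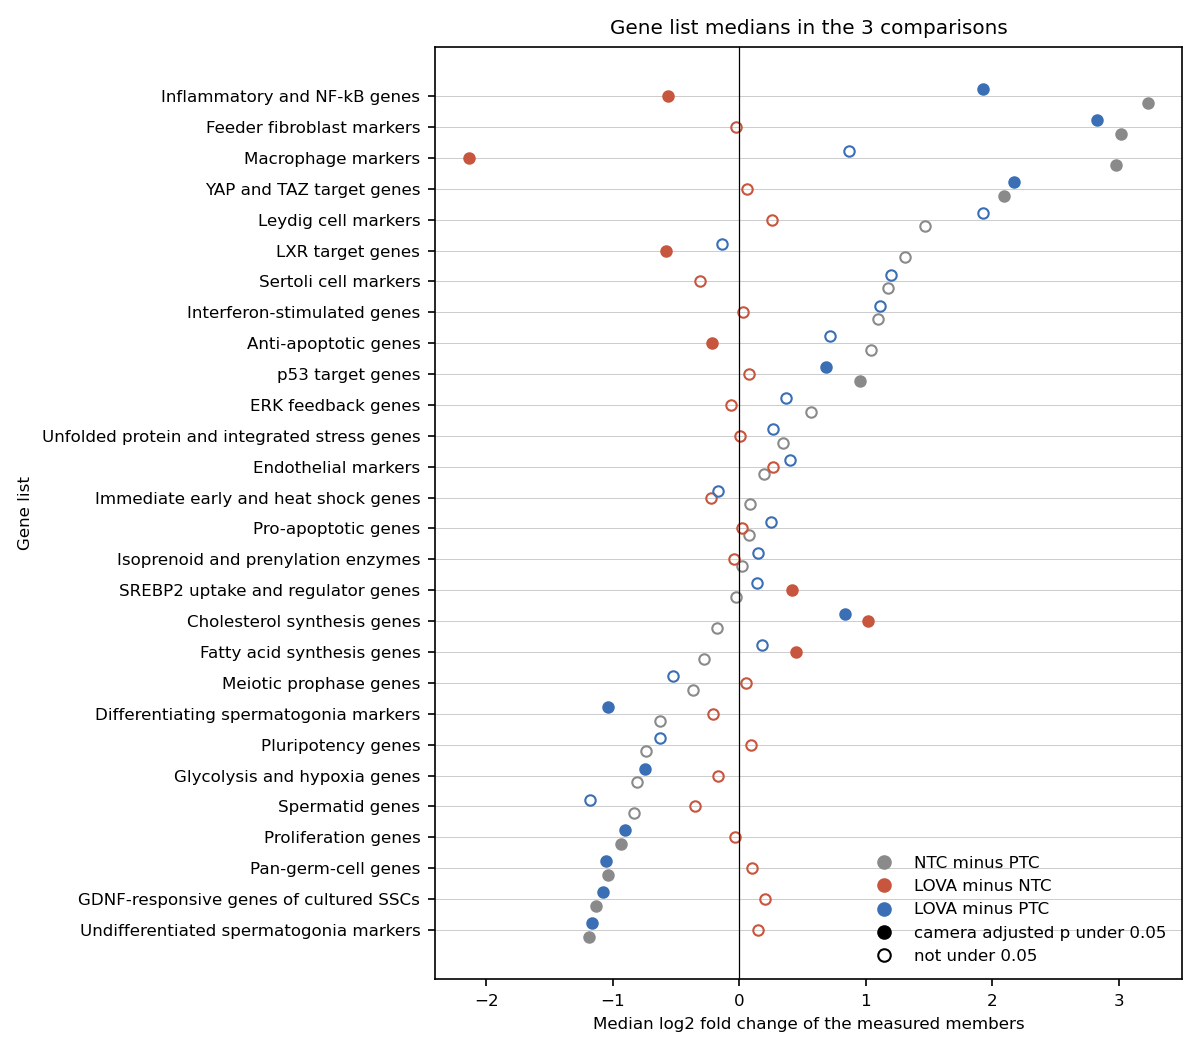
Median log2 fold change of the gene lists reported here in the 3 contrasts; filled points passed camera at a preset correlation, open points did not. Inflammatory genes were at 3.23 in NTC minus PTC and -0.56 in LOVA minus NTC, and cholesterol synthesis genes at -0.18 (0.89 with libraries scaled to the pan-germ-cell genes) and 1.02; proliferation genes in NTC minus PTC turned from -0.93 to 0.07 with that scaling.

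LOVA minus NTC shows what changed when lovastatin was added to the medium without GDNF. No single gene passed the test in the edgeR fit without pairing, which had 561 genes at an unadjusted p under 0.05, while a block by column letter called 18 higher and 72 lower, DESeq2 25 and 95 and limma-voom 0 and 4. In the lists, cholesterol synthesis genes were higher and macrophage markers lower in LOVA. All 20 cholesterol synthesis genes had positive fold changes, with a median log2 of 1.02 (1.21 between the A and 0.89 between the B libraries), and 17 were called higher adjusted over the list alone. The list passed camera (adjusted p = 4.48e-49) and fry (adjusted p = 0.0398), with an adjusted p of 0.0733 with an estimated correlation. Hmgcs1 was at 302 ± 49.9 CPM in NTC and 608 ± 68.0 in LOVA (SD, n = 2; log2 fold change 1.01, SE 0.18, adjusted p = 0.262 over all genes). Fdps, which makes farnesyl diphosphate, was at 1.05 (SE 0.20, adjusted p = 0.287). Hmgcs1 (ENSMUSG00000093930) lies on chromosome 13 from 119690379 to 119708260. Of the 12 SREBP2 uptake and regulator genes, 5 were higher adjusted over the list alone, including Insig1 (0.87, SE 0.17). Their median was 0.42 (camera adjusted p = 6.31e-07; adjusted p = 0.190 with an estimated correlation). All 12 fatty acid synthesis genes had positive fold changes, with a median of 0.45, and 2 were higher adjusted over the list alone (camera adjusted p = 8.61e-08; adjusted p = 0.104 with an estimated correlation). The 7 LXR targets, cholesterol efflux and transport genes, had negative fold changes, with a median of -0.58 and 1 lower adjusted over the list alone, Apoe (camera adjusted p = 6.31e-07; adjusted p = 0.104 with an estimated correlation). Feeder shares of the 2 groups were 2.28% and 2.21%, and the macrophage share went from 0.196% to 0.0427%; Apoe, at -2.09, fell about as far as the macrophage markers (median -2.14). These 4 list calls, by camera at the preset correlation, held without each of the 6 libraries in turn. That camera test does not measure the spread between libraries. By fry the SREBP2, fatty acid and LXR lists did not pass (adjusted p = 0.0842, 0.0927 and 0.0842).

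**Figure D4:**
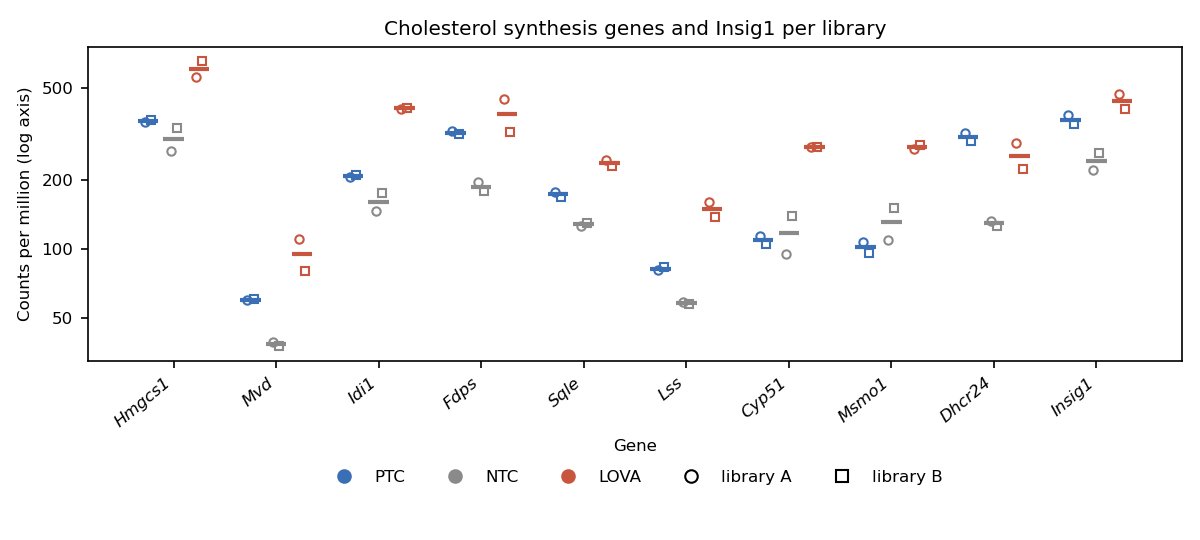
CPM on a log axis of cholesterol synthesis genes and their regulator Insig1; points are libraries (circle A, square B) and bars are group means (n = 2). Hmgcs1 was at 302 CPM in NTC and 608 in LOVA.

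All 10 macrophage markers were lower in LOVA than in NTC adjusted over the list alone, with a median of -2.14 (-2.01 between the A and -2.23 between the B libraries). The list passed camera (adjusted p = 4.12e-50) but not fry (adjusted p = 0.0589), and its adjusted p was 0.0733 with an estimated correlation. Lyz2, the lysozyme of macrophages, was at 1810 ± 365 CPM in NTC and 385 ± 73.1 in LOVA (log2 fold change -2.23, SE 0.22, adjusted p = 0.0589 over all genes), with a PTC mean of 187. Apoe was at 682 ± 140 and 160 ± 19.2 CPM (-2.09, SE 0.21, adjusted p = 0.0589), and Cd68, a lysosomal protein of macrophages, at -2.04 (SE 0.22, adjusted p = 0.0605). Of the 22 inflammatory genes, 20 had negative fold changes, with a median of -0.56 (-1.17 between the A and -0.27 between the B libraries) and a mean of -1.24, and 5 were lower adjusted over the list alone, which were Tnf, Cxcl2, Saa3, Il1a and Il1b. Camera gave the inflammatory list an adjusted p of 2.01e-15, and an adjusted p of 0.401 with an estimated correlation. The most abundant member, the chemokine Ccl7, was at -0.79 (SE 0.41, adjusted p = 1). Il1b had 61 counts in NTC and 0 in LOVA, at least 18.3-fold lower against a floor of 3 counts over the group, and 4 counts in PTC. The anti-apoptotic list had a median of -0.22 (camera adjusted p = 8.07e-03; adjusted p = 0.905 with an estimated correlation), and its 2 members lower adjusted over the list alone were the paralogs Bcl2a1b and Bcl2a1d. Bcl2a1d had 64 counts in NTC and 0 in LOVA, at least 19.2-fold lower against the same floor. The macrophage share of counts was 0.196% in NTC and 0.0427% in LOVA beside these lists. The anti-apoptotic list was no longer called without NTC B (adjusted p = 0.366) or without LOVA A (0.466). The list members singled out by the list-alone test beyond the 2 that the rule takes were named after their values were seen.

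**Figure D5:**
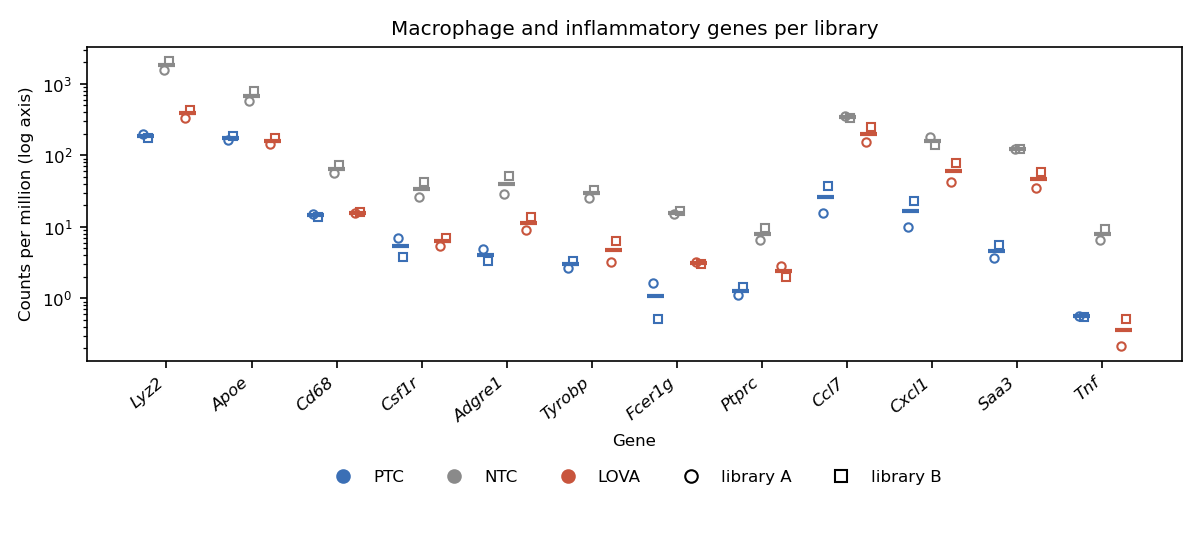
CPM on a log axis of macrophage and inflammatory genes; points are libraries (circle A, square B) and bars are group means (n = 2). Lyz2 was at 187 CPM in PTC, 1810 in NTC and 385 in LOVA.

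Self-renewal genes differed between LOVA and NTC by less than the test could call. Ret was at 61.2 ± 10.0 CPM in NTC and 84.8 ± 28.7 in LOVA (0.47, SE 0.30), Zbtb16 at 130 ± 6.39 and 172 ± 64.3 (0.41, SE 0.26), Gfra1 at 0.29 (SE 0.23), Etv5 at 0.36 (SE 0.31) and Bcl6b at 0.06 (SE 0.34; -0.08 with libraries scaled to the pan-germ-cell genes), each with an adjusted p of 1. GDNF-responsive genes had a median of 0.20 (camera adjusted p = 0.499), undifferentiated markers 0.14 (0.26 between the A and -0.14 between the B libraries; adjusted p = 0.411) and pan-germ-cell genes 0.10 (adjusted p = 0.533). With libraries scaled to the pan-germ-cell genes, Lhx1 was at 1.19 (SE 0.56) and Nefm at 1.12 (SE 0.59). Cxcr4 was at -1.17 (SE 0.69) and Pax7 at -1.20 (SE 0.54) with that scaling. None of these genes was called, and they were named here after their values were seen. Kit was at -0.32 (SE 0.36), and differentiating markers had a median of -0.21. Proliferation genes had a median of -0.03, with the test pointing up, and feeder markers -0.03. Isoprenoid and prenylation enzymes had a median of -0.04, a mean of 0.07 and a test pointing up, with Fdps higher adjusted over the list alone. Medians were 0.08 for p53 targets, 0.02 for pro-apoptotic genes, 0.06 for YAP targets, -0.07 for ERK feedback genes, -0.17 for glycolysis genes and -0.23 for immediate early and heat shock genes. For interferon-stimulated genes the median was 0.03 with a test pointing down, and for the stress list the median was 0.00248 and the mean -0.12. They were 0.05 for meiotic genes, 0.09 for pluripotency genes, -0.31, 0.25 and 0.27 for Sertoli, Leydig and endothelial markers, and -0.35 for spermatid genes. With libraries scaled to the pan-germ-cell genes the medians of the meiotic, pluripotency, pro-apoptotic and stress lists turned to -0.00400, -0.05, -0.03 and -0.07. Without LOVA B undifferentiated and pan-germ-cell markers were called higher by camera (adjusted p = 6.32e-04 and 3.94e-05), and without LOVA A pan-germ-cell genes were called lower (adjusted p = 0.0106) and differentiating markers too (1.88e-04). Without NTC A pan-germ-cell genes were called higher (adjusted p = 0.00385), and without NTC B differentiating markers were called lower (2.88e-04). Proliferation genes were called higher without NTC A (adjusted p = 0.00386) and without LOVA B (0.00177), and lower without NTC B (0.00573) and without LOVA A (0.00363). Meiotic genes were called without NTC A (0.00206), NTC B (0.0310, turned) and LOVA B (0.0128), interferon-stimulated genes without LOVA A (0.00623, turned) and LOVA B (0.00157), and pluripotency genes without LOVA B (0.0280). The immediate early list was called with a block by column letter (adjusted p = 0.0475) and without NTC B (0.0164) and LOVA A (0.0354), Leydig markers without NTC B (0.0482) and p53 targets without LOVA A (0.0158).

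In LOVA minus NTC edgeR called 0 genes higher and 0 lower, with a smallest adjusted p of 0.0589, and 561 genes had an unadjusted p under 0.05 (217 higher and 344 lower). DESeq2 called 25 higher and 95 lower, and limma-voom 0 higher and 4 lower. A block by column letter in edgeR called 18 higher and 72 lower. Among the lower were Lyz2, Apoe, Cd68 and Saa3, and among the higher Hmgcs1, Fdps, Insig1, Idi1 and Lss. These were named after their values were seen. The 4 genes of limma-voom were Apoe, C1qb, F13a1 and Lyz2, of which C1qb, a complement gene of macrophages, and F13a1, a clotting factor subunit, were named after their values were seen. Without LOVA A edgeR called 2 genes lower, F13a1 and Gm49339, and without LOVA B 1, F13a1.

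LOVA minus PTC shows what differed when lovastatin took the place of GDNF. Some self-renewal genes fell and many fibroblast, inflammatory and cholesterol synthesis genes rose in LOVA. Lhx1 fell from 11.8 ± 3.87 to 0.992 ± 0.309 CPM (-3.55, SE 0.46, adjusted p = 0.0167), Ret from 245 ± 65.2 to 84.8 ± 28.7 (-1.53, SE 0.30, adjusted p = 0.0190) and Zbtb16 by 1.17 (SE 0.26, adjusted p = 0.0230). Hmgcs1 rose by 0.76 (SE 0.18, adjusted p = 0.0263). Etv5 (-0.05), Gfra1 (-0.40), Bcl6b (-1.07, adjusted p = 0.0515) and Kit (-0.15) did not pass the test; with libraries scaled to the pan-germ-cell genes Etv5, Gfra1 and Kit turned to 0.96, 0.60 and 0.77, not called. Of the 13 GDNF-responsive genes 5 fell (6 adjusted over the list alone), with a median of -1.07 (camera adjusted p = 0.00171), and of the 19 undifferentiated markers 10 fell (12 lower and 1 higher adjusted over the list alone), with a median of -1.17 (adjusted p = 1.83e-05). Of the 19 pan-germ-cell genes 8 fell (16 adjusted over the list alone), with a median of -1.05 (adjusted p = 1.23e-05), and of the 24 proliferation genes 9 fell (14 adjusted over the list alone), with a median of -0.90 (adjusted p = 1.01e-05) that was -0.03 with libraries scaled to the pan-germ-cell genes. Of the 14 differentiating markers 4 fell and 1 rose, with a median of -1.04 (adjusted p = 0.0124), and of the 19 glycolysis genes 10 fell and 3 rose, with a median of -0.75 (adjusted p = 0.0274) that became 0.22 with that scaling. The medians of the GDNF-responsive, undifferentiated, differentiating and pan-germ-cell lists were then -0.19, -0.28, -0.16 and -0.17, the last largely set by the scaling itself. With that scaling Ret (-0.64, adjusted p = 0.154) and Zbtb16 (-0.29, adjusted p = 0.467) lost their calls, and Lhx1 kept its call at -2.67. With an estimated correlation the adjusted p was 0.663 for the differentiating markers and 0.609 for the other 5 lists. The pan-germ-cell share was 0.556% in PTC and 0.283% in LOVA. The glycolysis call was lost without PTC A (adjusted p = 0.126), NTC A (0.0526) or LOVA A (0.259), and the differentiating call without PTC B (0.0556) or LOVA B (0.057). Of the 114 called among the 125 named genes of this contrast, 77 lost their call without PTC A, 74 without LOVA B, 38 without PTC B, 19 without NTC B, 15 without NTC A and 13 without LOVA A.

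Of the 20 cholesterol synthesis genes 13 rose in LOVA over PTC (14 adjusted over the list alone), including Ebp (2.34), Sc5d (1.83) and Mvk (1.47), with a median of 0.84 (camera adjusted p = 1.70e-04; adjusted p = 0.609 with an estimated correlation). Ebp was also higher by 2.33 (SE 0.41) in NTC than in PTC, without lovastatin. In LOVA, Idi1 rose by 0.98 (SE 0.16), whereas the cholesterol exporters Abca1 and Abcg1 fell by 1.33 and 0.91. Abcg1 was at 0.03 with libraries scaled to the pan-germ-cell genes. Feeder markers rose in 13 of 21 (21 adjusted over the list alone; median 2.83, adjusted p = 9.56e-07), with a feeder share of 0.362% in PTC and 2.21% in LOVA. Inflammatory genes rose in 14 of 22 (16 adjusted over the list alone; median 1.92, adjusted p = 1.22e-06), led by Lcn2 (4.14) and Saa3 (3.32). YAP and TAZ targets rose in 12 of 22 with 1 lower (median 2.17, adjusted p = 2.35e-04) and p53 targets in 10 of 17 (median 0.69, adjusted p = 7.93e-05). For these 4 lists the adjusted p was 0.609 with an estimated correlation, and no list of this contrast passed by fry. Macrophage markers were not called (median 0.87, adjusted p = 0.114), though Lyz2 (1.04, SE 0.22) and Adgre1 (2.82-fold, log2 SE 0.40, adjusted p = 0.0334) rose; without PTC A the list was called (adjusted p = 0.0301). Of the genes reported here with a mean CPM of at least 5, the lowest fold changes were those of Barhl2 (-3.41) and Fgd5 (-3.32), followed by Mpzl2, Zic1, Foxi3, Foxo6 and Gstp2, the last a member of a gene family with close paralogs. The highest were Pakap (6.64), Ces1a (5.40), AY036118 of the ribosomal DNA locus (5.11), the peptidase Mme (5.05), Dnm3os, Kng1, Grem1 and Plac9b (4.91). EdgeR called 3192 genes higher and 1747 lower, of which 2739 and 749 changed at least 2-fold. Without PTC A the counts were 701 and 57, without PTC B 2069 and 259, without NTC A 2284 and 833, without NTC B 2140 and 809, without LOVA A 3580 and 3174 and without LOVA B 628 and 148. Of the 114 called named genes, 77 lost their call without PTC A and 74 without LOVA B.

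Many genes changed without GDNF were also changed with lovastatin in its place. Among called genes, 2821 were higher and 1452 lower than PTC in both NTC and LOVA, where independence gives 687 and 226. The shared count of 4273 fell to 1 without NTC B, 731 without PTC A, 763 without LOVA B, 2155 without PTC B and 2257 without NTC A. These falls are in calls at the threshold. Without NTC B the 115 called named genes of NTC minus PTC all kept the sign of their fold change. Both contrasts share the PTC libraries, so part of the excess of shared calls can come from those libraries. Called in opposite directions were 2 genes, named after their values were seen: F13a1 was higher in NTC (2.97) and lower in LOVA (-1.58), and Mvd, a mevalonate pathway enzyme, was lower in NTC (-0.65) and higher in LOVA (0.66). Across genes, which are not independent replicates, the fold changes correlated at r = 0.910, where the shared PTC libraries alone gave 0.483 (0.449 to 0.507 in 100 simulations), and their covariance was 1.69 against 0.122. For genes changed without GDNF and their change on adding lovastatin, 0 genes were called by edgeR in both contrasts, since none was called in the second (561 at an unadjusted p under 0.05); DESeq2 gave 105 in opposite directions and limma-voom 4. Those fold changes correlated at r = -0.343, where the shared NTC libraries alone gave -0.503 (-0.530 to -0.470). These r values cannot be compared. The simulated groups were unchanged, while the 5558 genes called in NTC minus PTC widen the spread of its fold changes. The covariance of the 2 sets of fold changes was -0.281 against -0.128 in the simulations, a difference of -0.153. The sign was the same in 41.6% of genes, against 33.2% in the simulations. Every simulated group held the mean of the 6 libraries, so its noise need not match that of the NTC libraries. None of these measures thus decides whether lovastatin moved the genes back.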

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

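Chosen only after the data were seen were the tests with libraries scaled to the pan-germ-cell genes, without the ribosomal DNA locus genes and with the feeder score as a covariate. No gene called in NTC minus PTC or LOVA minus PTC turned to the opposite call under the alternatives run for these contrasts, which the feeder covariate was not; LOVA minus NTC had no called gene to turn. For NTC minus PTC and LOVA minus PTC, RLE and upper-quartile scaling, the strict filter, limma-voom, DESeq2 and leaving out the ribosomal DNA locus genes gave counts within 1.5 times those reported. For LOVA minus NTC, no filter gave 44 higher and 147 lower, DESeq2 25 and 95, limma-voom 4 lower, and the feeder covariate 14 and 71; the cause was not tested except for the covariate. Genes in opposite directions in NTC minus PTC and LOVA minus NTC numbered 156 with no filter, 105 by DESeq2 and 4 by limma-voom. For LOVA minus PTC, no filter gave 2703 lower and a fit of the 2 compared groups alone 881 lower; the cause was not tested. Stricter thresholds lowered counts by construction. A change of at least 2-fold left 932 lower in NTC minus PTC and 749 lower in LOVA minus PTC. An adjusted p under 0.01 left 444 higher and 62 lower in NTC minus PTC. In LOVA minus PTC it left 0 higher and 0 lower by edgeR, with 7456 at an unadjusted p under 0.05 (DESeq2 3680 and 2443, limma-voom 3187 and 2162 at 0.05), and so 0 shared in direction with NTC minus PTC. Scaling to the pan-germ-cell genes left 40 lower in NTC minus PTC and 33 in LOVA minus PTC, since it raised the median of all genes by 1.05 and 0.98. Among the genes reported here that were called before it, that scaling turned the NTC minus PTC log2 fold changes of Dhcr7 to 0.16, Srebf2 to 0.086, Tmem97 to 0.072, Insig1 to 0.47, Acaca to 0.00417, Fasn to 0.00204, Acly to 0.17 and Fdps to 0.25, and that of Abcg1 in LOVA minus PTC to 0.028, none of them called. The labels pair no libraries, but the A minus B differences of the groups correlated at 0.247 to 0.366, so a difference shared by the letters is not excluded. A block by column letter gave 3632 lower in NTC minus PTC, 18 higher and 72 lower in LOVA minus NTC, 3466 lower in LOVA minus PTC, 79 genes in opposite directions and 6782 in the same direction. Leaving out 1 library gave 1 to 3635 higher and 0 to 3091 lower in NTC minus PTC (lowest without NTC B, highest without LOVA B). It gave 0 to 0 higher and 0 to 2 lower in LOVA minus NTC, and 628 to 3580 higher and 57 to 3174 lower in LOVA minus PTC (lowest without LOVA B and PTC A, highest without LOVA A). Genes in opposite directions then numbered 0 to 2, and in the same direction 1 to 5388. In LOVA minus NTC the camera direction turned, without NTC B, for meiotic (adjusted p = 0.0310) and proliferation genes (0.00573). Without LOVA A it turned for pan-germ-cell, interferon-stimulated and proliferation genes. The pan-germ-cell share of counts was 0.311% in NTC A, 0.205% in NTC B, 0.368% in LOVA A and 0.198% in LOVA B. The turn of the pan-germ-cell list thus followed the low share of the LOVA library that was left. For the other turned lists the cause was not tested. Over the 6 libraries left out, the adjusted p of these 4 lists ranged from 0.00206 to 0.832 (meiotic), 3.94e-05 to 0.537 (pan-germ-cell), 0.00157 to 0.987 (interferon-stimulated) and 0.00177 to 0.908 (proliferation). Of the lists called by camera (10, 8 and 12 in the 3 contrasts), an estimated correlation kept 0 and fry 3, 1 and 0; fry also called 3 further lists in NTC minus PTC. With 2 libraries per group and 200 genes changed, 7% to 13% of simulated 2-fold changes were recovered. Many changes of that size can thus be missed at this depth where few genes change; this rate does not carry over to NTC minus PTC and LOVA minus PTC, where smaller changes were called too.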

Other observations

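The tests of the germ cell share, with their bounds, and of the feeder share were chosen only after the results were seen; the tests of further macrophage genes and of the feeder covariate were added after the main results, with predictions written before they were run. Macrophage genes outside the fixed lists were also higher in NTC than in PTC. Over 20 further macrophage genes, 17 of them called adjusted over the list alone and 1 negative, such as the complement gene C1qb (9.48 CPM in PTC and 84.6 in NTC), the mannose receptor Mrc1 (14.2, 109 and 21.7 CPM in PTC, NTC and LOVA) and the protease Ctss (8.61, 78.0 and 14.5), the median log2 fold change in NTC minus PTC was 2.77. In LOVA minus PTC it was 0.49, and 17 of the 20 had a mean of at least 1 CPM in PTC.

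Other abundant transcripts, named after their values were seen, also separated PTC from the other groups. Spp1, which encodes the secreted protein osteopontin, rose on the log2 scale by 5.24 (SE 0.46) in NTC and 4.37 (SE 0.44) in LOVA. The imprinted growth genes H19 and Igf2 rose in NTC by 2.50 (SE 0.51) and 2.90 (SE 0.73) and in LOVA by 2.39 and 3.09, and Meg3 by 3.67 and 4.01. The X-inactivation RNA Xist rose 16-fold (log2 SE 0.52) in NTC and by 4.37 on the log2 scale (SE 0.53) in LOVA, and the nuclear RNA Malat1 by 3.88 and 4.55. Feeder markers rose beside them, with medians of 3.02 and 2.83 and a share of 0.362% in PTC, 2.28% in NTC and 2.21% in LOVA. Of the ribosomal DNA locus genes, whose reads can come from ribosomal RNA, Gm42418 rose by 4.14 and 4.24 and AY036118 by 4.99 and 5.11, while Gm26917 fell by 1.78 and 2.54. Of these 9 calls 8 were lost in NTC minus PTC without NTC B, all but AY036118 (adjusted p = 0.0379), and 6 in LOVA minus PTC without LOVA B (H19, Igf2, Meg3, Spp1, Malat1 and Gm26917). H19 and Igf2 were also lost in both contrasts without LOVA A and in NTC minus PTC without LOVA B, Igf2 in NTC minus PTC without NTC A and in LOVA minus PTC without NTC B, and Gm26917 in NTC minus PTC without PTC B.

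Many germ cell and self-renewal genes were lower in NTC than in PTC, and a smaller germ cell share of the RNA is a candidate explanation. All 19 pan-germ-cell genes had negative fold changes (100%), but this restates the pattern, so for these genes a smaller share cannot be told apart from lower expression per cell. Against that share as the whole account of Lhx1, its log2 fold change with libraries scaled to the pan-germ-cell genes was -3.86 (SE 0.54, adjusted p = 0.0269). For the other self-renewal genes it cannot be told apart from lower expression per cell: 0 stayed called lower with that scaling by edgeR, the 1 tool run on it (4 at an unadjusted p under 0.05), and Bmi1 and Cxcr4, named after their values were seen, were called higher. The median of all 30 members, Lhx1 included, went from -1.16 to -0.14 (median SE of single genes 0.33 and 0.42), and that of the 16 called before from -1.51 to -0.49 (median SE of single genes 0.32 and 0.31), but these were picked for being low, so what remains in them decides nothing. Absence of GDNF, the biological difference in the design, acting within germ cells, on their number, or both, stays open and was not tested.

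All 10 macrophage markers and 5 of the 22 inflammatory genes were lower in LOVA than in NTC adjusted over each list alone. Over all genes tested none was called. Neither list passed camera with an estimated correlation (adjusted p = 0.0733 and 0.401) or fry (adjusted p = 0.0589 and 0.561). Fewer macrophages among the cells is a candidate explanation. The further macrophage genes were lower in LOVA by a median log2 fold change of -2.23 (quartiles -2.39 and -1.75), with 20 of 20 negative and 16 called adjusted over the list alone, close to the -2.14 of the fixed macrophage markers. Against a smaller feeder share as the source, the feeder markers had a median of -0.029 where the inflammatory list had -0.56. Lower expression of these genes within macrophages, and an effect of lovastatin on either, stay open and were not tested. The labels state no source for macrophages, and whether these transcripts came from macrophages was not tested.

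No gene was called by edgeR in LOVA minus NTC (561 at an unadjusted p under 0.05, 25 higher and 95 lower by DESeq2, 4 lower by limma-voom), and a feeder share that differs between the A and B libraries may have widened the spread. With the feeder score as a covariate 85 genes were called, 14 higher and 71 lower, and the median quasi-dispersion went from 0.586 to 0.432. Part of such a fall comes with any added covariate or block, since fewer residual degrees of freedom remain. No unrelated covariate was run for comparison, so the size of that part is not known. The 14 included Idi1 (1.36), Lss (1.35) and Hmgcs1 (1.02), and the 71 included Lyz2 (-2.23), Apoe (-2.08) and C1qb (-2.50), named after their values were seen; 77 of the 85 were also called by DESeq2 without the covariate. A block by column letter lowered the median quasi-dispersion further, to 0.343, and called 18 higher and 72 lower, 76 of them shared with the covariate. The B library had the larger feeder share in each of the 3 groups, so these fits do not separate the feeder share from another difference between A and B libraries, which stays open.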
